A study of Homo sapiens with 8 samples.

How the data were processed

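Total RNA of Rh30 cells was measured on 8 Affymetrix gene-level arrays, 1 per sample, in 4 groups of 2: vehicle or rapamycin, each with a lentiviral hairpin against GFP (sh GFP) or against p73 (sh p73). Groups, letters, doses and times were taken from the labels. Per the labels, the authors summarised the arrays with ExonPlier16 in GeneSpring GX 9.0.6 at the level of core meta probe sets and set each probe set relative to its median over all samples. The deposited values are therefore log2 values centred per probe set: a value of 0 is the median of the 8 arrays, differences between arrays are kept, and no level that could be set against another probe set or against background remains. Base 2 is the convention of that software and is not given in the sources used here, and neither is any normalization between arrays. In the deposited values, array medians lay between -0.0248 and 0.032 and single values between -1.93 and 1.22, and no 2 arrays were copies of each other.

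A second deposited table holds genomic intervals in 5 tracks: peaks and intervals headed Veh, peaks and intervals headed Rap, and active regions. The score of each peak is the authors' own value, deposited without a scale. The assay, cells, protein, caller, replicates and genome build behind the tracks are not given in the sources used here. Intervals on chromosomes 3 and 19 end at 199066645 and 63776791, beyond the last annotated genes of GRCh38.p14 at 198230776 and 58599484, so the tracks are not on that build. No interval was assigned to a gene, and the planned exact test of intervals at changed genes was not run.

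Of 28869 probe sets, 19310 have 1 gene symbol in the platform annotation, 1752 have several and 7807 have none. By Entrez identifier, 19279 of the single symbols were found in the reference table of GRCh38.p14, and 0 symbols needed updating. Probe sets of 1 gene were averaged before any fit, which concerned 685 genes, and left 27936 features for testing, of which 18377 are genes with 1 symbol. Features read by a probe set with several symbols were tested and not named. Histones, ribosomal proteins and other near-identical families can share probes, so values of single members are uncertain.

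Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited values, with Benjamini-Hochberg adjustment over the 27936 features and a threshold of 0.05. All 8 arrays entered each fit and shared 1 estimate of the spread. The 4 groups were fitted as group means for all 6 pairwise comparisons and for the interaction. Rapamycin over both hairpins and knockdown over both treatments came from an additive model of 4 arrays against 4, and the difference between p73 constructs from a model with letter, treatment and a term per construct. Errors are standard errors (SE) of these fits. The precision is limited by the number of arrays. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

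In the sh p73 groups replicate A carries construct sh p73-1 and replicate B construct sh p73-2, so their spread includes the difference between constructs. A single hairpin, sh GFP, is the comparator throughout.

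The comparisons, their alternatives, the rule for naming genes and 32 gene lists with 1031 entries, 956 of them measured, were fixed before the data were examined. The rule names, among genes past the threshold whose arrays do not overlap between groups, the 10 largest rises and 10 largest falls in 4 main comparisons and 5 of each elsewhere. Where fewer than 5 passed, the 5 with the smallest p are given as not past the threshold. Up to 4 members with the smallest p are named for each list past its test or with at least 2 members past the threshold, and TP73 and MTOR always. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 32 lists, and again with an estimated correlation. Limma's fry, which asks whether a list moves 1 way on balance without comparing it with other genes, was an alternative.

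In simulated data 200 of 27936 features were changed by 1.5-, 2- or 3-fold in about equal numbers, with noise independent between features. Changes of 1.5-fold were recovered at 80.9% for rapamycin in sh GFP cells and 82.7% for knockdown in vehicle. The shares were 98.8% for rapamycin over both hairpins and 97.6% for knockdown over both treatments. For the interaction and the construct difference the shares were 26.9% and 27.2% at 1.5-fold, and 95.5% and 92.5% at 2-fold. Between 8.8 and 13.8 unchanged features were called on average in each simulated comparison. The larger simulated changes ease the adjusted threshold, so the shares at 1.5-fold are not the power of the real comparisons.

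Alternatives were quantile normalization of the deposited values, array medians set to 0, probe sets with 1 symbol only and each probe set by itself. Further ones were robust eBayes, array weights, fits of only the 2 groups compared, a 1.5-fold minimum and an adjusted p under 0.1. The last were the letter as a term, each construct by itself, and leaving out each array in turn. When 1 array is left out, the remaining array of that group is assumed to vary like the other groups. Intervals were called overlapping from 1 bp on. Blocks of chromosomes are the 7 runs within which the deposited table sorts chromosomes by name. Exact binomial intervals of 95% on shares of intervals cover counting error only. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.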

Results

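Gene expression was measured in Rh30, an established line of alveolar rhabdomyosarcoma, a tumour of muscle-like cells driven by the PAX3-FOXO1 fusion. Cells carried lentiviral hairpins for 3 days and then received vehicle or 40 nM rapamycin, an inhibitor of the mTOR kinase complex 1, in medium without serum for 24 hours. There were 8 arrays, 2 in each of 4 groups: vehicle with sh GFP, vehicle with sh p73, rapamycin with sh GFP and rapamycin with sh p73. The labels state the aim as finding genes that mTOR and p73 act on. Values are log2, relative to the median of the 8 arrays for each probe set. Across features, replicate arrays correlated at r = 0.287 in vehicle sh GFP, 0.284 in vehicle sh p73, 0.328 in rapamycin sh p73 and 0.038 in rapamycin sh GFP. Since values are centred, r compares deviations from the median and not signal levels. With vehicle sh GFP A and B, rapamycin sh GFP A correlated at 0.242 and 0.133, above its r with its own replicate. Rapamycin sh GFP B gave -0.126 and -0.037. On the leading principal component, with 33.3% of the variance, the 4 sh GFP arrays lay between -20.44 and -0.96 and the 4 sh p73 arrays between 4.32 and 22.06.

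The targeted gene was lower in every sh p73 array. TP73, which encodes the p53 family transcription factor p73, stood at 0.55 and 0.54 in vehicle sh GFP and at 0.47 and 0.32 in rapamycin sh GFP. It stood at -0.79 (sh p73-1) and -0.32 (sh p73-2) in vehicle, and at -0.57 and -0.38 in rapamycin. Over both treatments TP73 fell by 0.98 ± 0.11 on the log2 scale (SE, 4 arrays against 4, adjusted p = 0.00291 by limma). Against the sh GFP arrays of their own letter, the change was -1.19 for sh p73-1 (adjusted p = 0.0343) and -0.77 for sh p73-2 (adjusted p = 0.0785), and the difference between constructs had an adjusted p of 0.678. Rapamycin left TP73 at a log2 change of -0.03 ± 0.11 (adjusted p = 0.946). MTOR, the kinase gene, changed by -0.02 ± 0.05 with knockdown (adjusted p = 0.877) and by -0.03 ± 0.05 with rapamycin (adjusted p = 0.889).

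Knockdown of p73 was followed by more rises than falls. The largest rise was that of PSAP, which encodes prosaposin, the precursor of the lysosomal saposins, at a log2 change of 1.79 ± 0.07 or 3.45-fold (adjusted p = 2.13e-05). It was present with both constructs, at 1.93 and 1.65. KIFBP, a kinesin-binding protein gene, rose 2.15-fold, OLFML3, a secreted olfactomedin-like protein gene, 2.09-fold and DHRS2, a dehydrogenase gene, 2.07-fold. ANKRD36BP1, LRRC17, SFT2D2, PLIN3 (a lipid droplet coat protein), TFPI (tissue factor pathway inhibitor) and MFAP4 (a microfibril protein) rose by log2 0.96 to 0.85. The largest falls after TP73 were those of SORCS2, a sortilin-family receptor gene, at -0.86 ± 0.09, and MYBPHL, a myosin-binding protein gene, at -0.75 ± 0.07. MDM2, the ubiquitin ligase gene that p53 and its relatives induce, fell by 0.58 ± 0.07 (adjusted p = 0.00358), and DNMT3A, a DNA methyltransferase gene, fell by 0.56. TMEM40, SMPDL3A, S100A11, HS3ST2 and FOXN3 fell by 0.72, 0.64, 0.58, 0.57 and 0.57; HS3ST2 passed in 1 of the 8 fits that left out an array.

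In all, 836 features passed over both treatments, 705 higher and 131 lower. After quantile normalization the split was 818 higher and 293 lower. The count was 541 without vehicle sh GFP A, 198 without vehicle sh GFP B, 298 without vehicle sh p73 A, 184 without rapamycin sh GFP A, 284 without rapamycin sh p73 A and 292 without rapamycin sh p73 B. PSAP, KIFBP, OLFML3, TP73, MDM2, SORCS2, MYBPHL and DNMT3A passed in all 8 such fits.

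**Figure D1:**
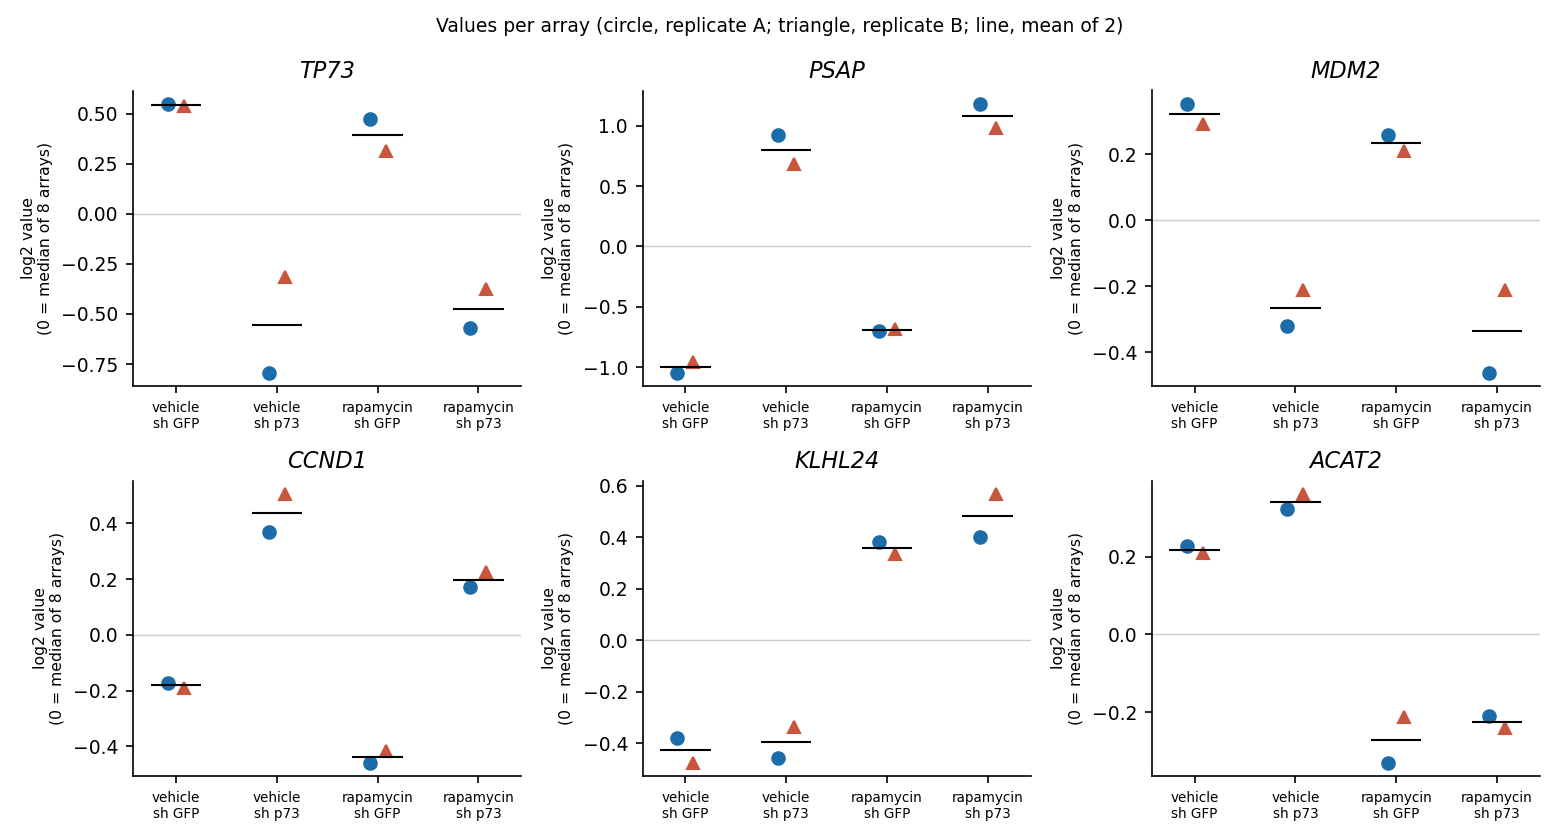
Deposited log2 values (vertical axes, 0 is the median of the 8 arrays) of 6 genes in the 4 groups; circles are replicate A, triangles replicate B and lines the mean of 2 arrays. TP73 and MDM2 were lower, and PSAP and CCND1 higher, in all 4 sh p73 arrays than in their sh GFP counterparts, while KLHL24 was higher and ACAT2 lower in all 4 rapamycin arrays.

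Among cell cycle genes 7 rose after knockdown. Of 47 G2/M genes 4 rose and 43 did not pass, and 7 rose adjusted over the list alone. UBE2C, a ubiquitin-conjugating enzyme of mitosis, rose by 0.50, BUB1B, a spindle checkpoint kinase, by 0.42, and KIF14 and HMMR by 0.37 and 0.29. The list was shifted upwards by camera (adjusted p = 0.000344), but not past the threshold with an estimated correlation (adjusted p = 0.688 with an estimated correlation). Of 48 G1/S and replication genes 3 rose: CCND1 (cyclin D1) by 0.63, GMNN (geminin) by 0.37 and GINS1, part of the replicative helicase, by 0.30. Adjusted over the list alone, 7 rose and 1 fell (camera adjusted p = 0.000415, adjusted p = 0.688 with an estimated correlation). UBE2C and CCND1 passed in all 8 fits that left out an array, while BUB1B passed in 6, KIF14 in 4, HMMR in 2, and GMNN and GINS1 in 1.

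Extracellular matrix genes held the most calls of any list. Of 41, 8 rose, 1 fell and 32 did not pass, and 15 rose and 2 fell adjusted over the list alone. FBN1 (fibrillin) rose by 0.72, COL12A1, a collagen chain, by 0.74 and MMP14, a membrane-bound matrix protease, by 0.50, whereas ELN (elastin) fell by 0.38. FBN1 and MMP14 passed in all 8 fits that left out an array, COL12A1 in 7 and ELN in 6. The camera adjusted p was 0.0037, and the adjusted p = 0.688 with an estimated correlation. Of 33 immediate early and growth factor response genes 4 rose and 0 fell (9 and 2 adjusted over the list alone): DUSP6, a phosphatase of ERK, by 0.59, CCN1 by 0.60, ID1 by 0.45 and KLF2 by 0.33. Of 37 amino acid synthesis and ATF4 genes 3 rose (7 adjusted over the list alone), namely SLC1A4 by 0.34, PSAT1 by 0.37 and CARS1 by 0.36. The camera adjusted p was 0.016 for both lists, and the adjusted p = 0.688 with an estimated correlation; after quantile normalization the ATF4 list had an adjusted p of 0.0747. DUSP6 passed in all 8 fits that left out an array, CCN1 in 5, SLC1A4 in 3, and ID1, KLF2, PSAT1 and CARS1 in 1. Of 45 autophagy genes 3 rose, ATG4A by 0.68, UVRAG by 0.38 and ATG2B by 0.34, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.688 with an estimated correlation). These 3 passed in 8, 7 and 4 of the 8 fits. Among 41 histone genes limma called 0, with 5 higher and 1 lower at an unadjusted p under 0.05 (camera upwards, adjusted p = 0.0317, 0.15 after quantile normalization, adjusted p = 0.688 with an estimated correlation).

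Some fusion target and muscle genes fell. Of 20 PAX3-FOXO1 targets 4 fell, 16 did not pass and the count adjusted over the list alone was also 4. These were ABAT at -0.45, MYOG (myogenin, which switches on muscle differentiation) at -0.42, KCNN3 at -0.36 and MYCN at -0.28. The camera adjusted p was 0.0037, and the adjusted p = 0.688 with an estimated correlation. Of 48 muscle differentiation genes 3 fell, MYOG, TPM2 (a tropomyosin, -0.31) and TNNI1 (a troponin, -0.29), with 1 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.00572, adjusted p = 0.688 with an estimated correlation). Among 42 ribosomal protein genes RPL22 rose by 0.46 (past in 1 of the 8 fits that left out an array), although the list was shifted downwards (camera adjusted p = 0.00302, adjusted p = 0.688 with an estimated correlation), and 0 were called by limma adjusted over the list alone, with 1 higher and 5 lower at an unadjusted p under 0.05. Markers of blood cells, fixed as a check for other cell types, had 0 of 14 called by limma, 4 lower at an unadjusted p under 0.05 and 2 lower adjusted over the list alone. Their camera adjusted p was 0.0436, with 0.0582 after quantile normalization and an adjusted p = 0.688 with an estimated correlation. ABAT passed in all 8 fits that left out an array, KCNN3, MYOG and TPM2 in 3, TNNI1 in 1 and MYCN in 0.

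Genes of the p53 network moved in both directions. Of 43 p53 family targets 4 rose, 1 fell and 38 did not pass, with 5 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.658). ZMAT3, an RNA-binding protein gene, rose by 0.45, CCNG1 (cyclin G1) by 0.33 and JAG1, a Notch ligand gene, by 0.29, while MDM2 fell. Of 9 family members 2 fell, TP73 and MDM2 (camera adjusted p = 0.329). Of 33 apoptosis genes 3 rose, with 5 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.658): APAF1, which forms the apoptosome, by 0.63, the anti-apoptotic MCL1 by 0.41 and CASP2 (caspase 2) by 0.34. MDM2 and APAF1 passed in all 8 fits that left out an array, ZMAT3 in 7, MCL1 in 4, JAG1 and CASP2 in 2 and CCNG1 in 1. Camera adjusted p-values of the other lists were 0.0971 for interferon response, 0.105 for hypoxia, 0.106, 0.217 and 0.749 for epithelial, neural and endothelial markers, 0.164 for ribosome biogenesis and 0.329 for translation factors. They were 0.353 for the unfolded protein response, 0.526 for lysosome, 0.619 for oxidative phosphorylation, 0.735 for fatty acid synthesis and for FOXO targets, 0.764 for cholesterol synthesis, 0.801 for the mTOR and insulin pathway, 0.913 for the pentose phosphate pathway, 0.919 for NF-kB, and 0.929 for glycolysis and for nucleotide synthesis.

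Within vehicle alone, knockdown raised PSAP by 1.80 ± 0.11, KIFBP by 1.23, LRRC17 by 1.07 and SFT2D2 by 1.04, and OLFML3 2.3-fold. PLIN3, PTPN22 (a phosphatase gene), MFAP4, TFPI and PBDC1 rose by 0.97 to 0.95. Falls were led by TP73 at -1.10 ± 0.15 (adjusted p = 0.0196), CTDP1-DT at -1.01, SORCS2 at -0.91, TMEM40 at -0.88 and MYBPHL at -0.83. SPDYE3, LPAR3 (a lysophosphatidic acid receptor), ANKRD40CL, OR6P1 and SMPDL3A fell by 0.76 to 0.66. Here 282 features passed, 186 higher and 96 lower, against 210 and 59 after quantile normalization and 418 and 408 with only probe sets of 1 symbol. At an unadjusted p under 0.05 there were 2407 higher and 4227 lower. In a fit of only these 2 groups limma called 0. Of the lists, G2/M genes (camera adjusted p = 2.79e-05), ATF4 genes (0.000227), G1/S genes (0.000311), autophagy (0.0017), histones (0.00496), extracellular matrix (0.00922), interferon response (0.0339) and oxidative phosphorylation (0.0391) were shifted upwards and PAX3-FOXO1 targets downwards (0.00508). The smallest adjusted p = 0.649 with an estimated correlation. Camera compares a list with all other genes, and the median change over all features was -0.0375 in this comparison. Without each array in turn the count was 3 and 29 (vehicle sh GFP A and B), 4 and 20 (vehicle sh p73 A and B), 183 and 183 (rapamycin sh GFP A and B) and 52 and 52 (rapamycin sh p73 A and B).

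Within rapamycin, PSAP rose by 1.77 ± 0.11 (adjusted p = 0.00182), ANKRD36BP1 by 1.14, KIFBP by 0.98, OLFML3 by 0.92 and CNP, a myelin phosphodiesterase gene, by 0.84, while MYBPHL and S100A11 fell by 0.66 and 0.55. TP73 stood at -0.87 ± 0.15 and did not pass (adjusted p = 0.0831). In this arm 48 features passed, 46 higher and 2 lower (52 and 18 after quantile normalization), and 1 passed in a fit of only these 2 groups. Of these, 35 of the 46 and both of the 2 were also called in vehicle, where independent lists would share 0.306 and 0.00687. The 2 comparisons share the estimate of the spread of each feature, so their calls are not independent and the excess is overstated. The knockdown effects in the 2 arms, which share no array, correlated across features at r = 0.393 (rho = 0.342; genes are not independent replicates), and at 0.18 without rapamycin sh GFP A. Oxidative phosphorylation and ribosomal protein genes were shifted downwards (both camera adjusted p = 1.8e-05, adjusted p = 0.615 with an estimated correlation), as were ribosome biogenesis genes (0.000204, adjusted p = 0.586 with an estimated correlation). Limma called 0 members of these 3 lists, with 4, 3 and 2 lower and 0, 1 and 0 higher at an unadjusted p under 0.05. The shifts are relative to all other genes, and the median change over all features was 0.0418 here against -0.0375 in vehicle. The count was 4 without vehicle sh GFP A or B, 29 without vehicle sh p73 A or B, 2 and 0 without rapamycin sh GFP A and B, and 0 and 1 without rapamycin sh p73 A and B.

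With rapamycin over both hairpins, KLHL24, a kelch-like adaptor gene, rose by 0.83 ± 0.06 or 1.78-fold (adjusted p = 0.00711), CREBRF, a transcription regulator gene, by 0.76 and FBXO32 (atrogin-1, a muscle ubiquitin ligase) by 0.73. FBXL20, an F-box protein gene, and HBP1, a transcriptional repressor gene, rose by 0.69 and 0.65, and UBALD2, HYKK, JMY, BCAS3 and MTURN by 0.53 to 0.50. TNC (tenascin C, a matrix glycoprotein) fell by 0.70 ± 0.07 (adjusted p = 0.0137), followed by RNU5E-1, a U5 spliceosomal RNA gene, at -0.66 and FCRLA at -0.57. Enzymes of sterol synthesis were among the falls, with ACAT2 at -0.53, DHCR7 at -0.41 and SQLE (squalene epoxidase) at -0.39, beside KLHL13 at -0.43. In all, 25 features passed, 16 higher and 9 lower, against 13 and 13 after quantile normalization, 75 and 67 with only probe sets of 1 symbol, and 329 and 336 with array weights. The count was 2 and 0 without vehicle sh GFP A and B, 11 and 0 without vehicle sh p73 A and B, 0 and 7 without rapamycin sh GFP A and B, and 0 and 1 without rapamycin sh p73 A and B. Of the 19 genes named here as past the threshold, 9 passed in 0 of these 8 fits, DHCR7 and SQLE among them. ACAT2 passed in 1, and KLHL24 in 4, the most of any.

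With rapamycin, biosynthetic and proliferation lists were shifted downwards by camera at the preset correlation and not with an estimated one. Of 19 cholesterol synthesis genes 3 fell, and 15 fell adjusted over the list alone (median log2 change -0.27, camera adjusted p = 1.88e-19, adjusted p = 0.0543 with an estimated correlation). Among 39 ribosome biogenesis genes 22 fell adjusted over the list alone (median -0.17, camera adjusted p = 6.33e-20), with LYAR at -0.41 and NOP2 at -0.32. Among 41 histones the number was 19 (median -0.16, camera adjusted p = 1.36e-17), with H3C11 at -0.32, and among 37 ATF4 genes, which include aminoacyl-tRNA synthetases, also 19 (median -0.16, camera adjusted p = 1.29e-16), with YARS1 at -0.43 and PSAT1 at -0.41. Among 18 fatty acid synthesis genes it was 8 (median -0.18, camera adjusted p = 3.81e-11), with FASN (fatty acid synthase) at -0.46 and SCD at -0.34. Among 48 G1/S genes it was 7 (median -0.11, camera adjusted p = 5.45e-14), with GINS2 at -0.31 and CCND1 at -0.25, and among 20 nucleotide synthesis genes 5 (median -0.11, camera adjusted p = 4.65e-07). For these 6 lists the adjusted p = 0.105 with an estimated correlation. Over all features limma called 0 of their members, with 24, 23, 19, 10, 20 and 7 lower and 0 higher at an unadjusted p under 0.05.

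Lists of energy metabolism were shifted downwards by camera at the preset correlation, without a member past the threshold over all features. Oxidative phosphorylation genes (44, camera adjusted p = 2.3e-12, adjusted p = 0.252 with an estimated correlation) had 3 lower members adjusted over the list alone, and COX7B stood at -0.30. Glycolysis genes (20, camera adjusted p = 3.93e-06, adjusted p = 0.225 with an estimated correlation) had 8 lower and 1 higher, with HK2 (hexokinase 2) at -0.37 and LDHA at -0.31. The pentose phosphate list had 1 of 10 lower (camera adjusted p = 0.0463, 0.073 after quantile normalization, adjusted p = 0.217 with an estimated correlation). G2/M genes (camera adjusted p = 5.47e-08) and the unfolded protein response (0.000902) were shifted downwards too, each with an adjusted p = 0.295 with an estimated correlation. They had 0 called members adjusted over the list alone. Over all features limma called 0 members of these 5 lists, with 16, 9, 3, 8 and 4 lower and 0, 1, 0, 0 and 1 higher at an unadjusted p under 0.05.

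Lists of catabolism and muscle were shifted upwards by camera at the preset correlation and not with an estimated one. Of 23 FOXO targets 3 rose, FBXO32, CCNG2 (cyclin G2) by 0.43 and TXNIP, a regulator of glucose uptake, by 0.40, and 4 rose adjusted over the list alone (camera adjusted p = 0.00447, adjusted p = 0.158 with an estimated correlation). FBXO32 passed in 1 of the 8 fits that left out an array, and CCNG2 and TXNIP in 0. Among 48 muscle differentiation genes 5 rose adjusted over the list alone (camera adjusted p = 4.14e-05, adjusted p = 0.2 with an estimated correlation), with KLHL41 at 0.63, TPM1 at 0.37 and MYMK (myomaker, which acts in the fusion of muscle cells) at 0.34. Among 36 lysosomal genes 8 rose adjusted over the list alone (camera adjusted p = 0.00861, adjusted p = 0.413 with an estimated correlation), and among 45 autophagy genes 3 (camera adjusted p = 0.00463, adjusted p = 0.353 with an estimated correlation), with NBR1, an autophagy receptor gene, at 0.39 and ATG13 at 0.29. Ribosomal protein genes (camera adjusted p = 0.000659, adjusted p = 0.498 with an estimated correlation) and interferon response genes (0.0361, adjusted p = 0.487 with an estimated correlation) were shifted upwards with 0 members called adjusted over the list alone. Over all features limma called 0 members of the muscle, lysosome, autophagy, ribosomal protein and interferon lists, with 16, 10, 13, 3 and 4 higher and 0, 1, 0, 0 and 0 lower at an unadjusted p under 0.05. Camera adjusted p-values of the remaining lists were 0.0858 for translation factors, 0.159 for epithelial markers, 0.263 for hypoxia, 0.605 for extracellular matrix, 0.628 for neural markers, 0.811 for blood markers, and 0.794 for p53 family targets, the mTOR and insulin pathway and endothelial markers. They were 0.969 for p53 family members, NF-kB, apoptosis, immediate early genes and PAX3-FOXO1 targets.

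**Figure D2:**
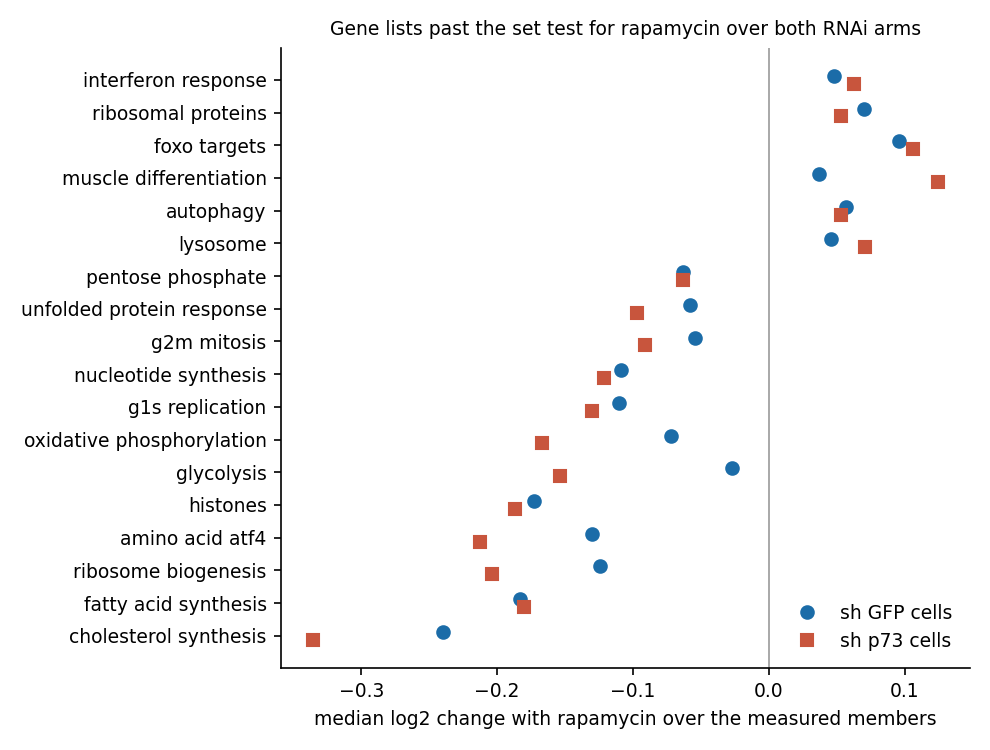
Median log2 change with rapamycin over the measured members (horizontal axis) of the 18 gene lists past camera with the preset correlation for rapamycin over both hairpins; circles are sh GFP cells and squares sh p73 cells, each 2 arrays against 2. All 18 medians lie on the same side of 0 in both, from -0.34 for cholesterol synthesis to 0.13 for muscle differentiation, both in sh p73 cells. The lists were chosen on the fit over both hairpins, which favours the same side in both. Camera compares a list with all other genes, so the side of 0 is not what it tested. The median change over all features was -0.0346 in sh GFP cells and 0.0621 in sh p73 cells.

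In sh GFP cells alone, limma called 0 features for rapamycin, with 2498 at an unadjusted p under 0.05 and a smallest adjusted p of 0.226. The leading genes, not past the threshold, were KLHL24 at 0.79 ± 0.09, CREBRF at 0.86, HBP1 at 0.67, FBXL20 at 0.60 and SMIM14 at 0.74, and, lower, SPIN2A at -0.58, FCRLA at -0.55, LSS (lanosterol synthase) at -0.49, FASN at -0.58 and MAJIN at -0.55. Cholesterol synthesis genes were the list with the smallest camera p (adjusted p = 2.8e-10, adjusted p = 0.432 with an estimated correlation), and 8 of 19 were lower adjusted over the list alone. In sh p73 cells 4 features passed, 3 higher and 1 lower, among them KLHL24 at 0.88 and FBXL20 at 0.77, with an adjusted p of 0.0486 each. Whichever of the 8 arrays was left out, and after quantile normalization, the count was 0. TNC at -0.76 and PSAT1 at -0.53 did not pass there (adjusted p = 0.144 and 0.156). Ribosome biogenesis genes led the lists (camera adjusted p = 1.55e-18, adjusted p = 0.172 with an estimated correlation). Across features the 2 rapamycin effects, which share no array, correlated at r = 0.103 (rho = 0.065), with -0.058 without vehicle sh GFP B and -0.045 without rapamycin sh GFP A. The interaction, which tests the difference between them, gave 0 features by limma, with 3165 at an unadjusted p under 0.05 and a smallest adjusted p of 0.182 (SPDYE3 at 0.96 ± 0.12).

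Rapamycin with sh p73 was compared with vehicle sh GFP. PSAP rose by 2.08 ± 0.11 (adjusted p = 0.000467), PKD1L1-AS1 by 1.30, CREBRF by 1.16, LRRC17 by 1.15 and KIFBP by 1.11, while TP73, FCRLA, ABAT, S100A11 and SORCS2 fell by 1.02, 1.00, 0.78, 0.77 and 0.77. CCN1 rose by 1.03, and FASN, LSS and HMGCS1, enzymes of lipid synthesis, fell by 0.57, 0.51 and 0.65. In this comparison 479 features passed, 404 higher and 75 lower (473 and 165 after quantile normalization). Ribosome biogenesis genes had 1 of 39 lower (NOP2, -0.46) and 12 lower adjusted over the list alone (camera adjusted p = 8.52e-12, adjusted p = 0.473 with an estimated correlation). The count was 2 and 1 without vehicle sh GFP A and B, 202 without rapamycin sh GFP A or B, and 3 and 1 without rapamycin sh p73 A and B. In the other crossed pair, rapamycin sh GFP against vehicle sh p73, 289 features passed, 61 higher and 228 lower. CCND1 was lower by -0.88, PSAT1 by -0.77, DUSP6 by -0.76 and TNC by -0.84, and MYOG was higher by 0.67. G1/S genes had 4 of 48 lower and 20 lower adjusted over the list alone (camera adjusted p = 6.94e-12, adjusted p = 0.283 with an estimated correlation). There the count was 146 without vehicle sh GFP A or B, 0 and 3 without vehicle sh p73 A and B, 0 without rapamycin sh GFP A or B, and 77 without rapamycin sh p73 A or B.

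Rapamycin in sh GFP cells and knockdown in vehicle share the vehicle sh GFP arrays. Their effects correlated across features at r = 0.457 (rho = 0.453), where unchanged groups against shared controls gave a simulated r of 0.5 over 100 draws. The simulated value follows in advance from groups of equal size and spread that share a control. Leaving out 1 array moved r to 0.216 without rapamycin sh GFP B and to 0.631 without vehicle sh GFP B. The simulated r is for 2 arrays in each group, so it is no standard for these 2 values. The covariance was 0.0129 against a simulated 0.00613, a difference of 0.00676. With 1 control array for each comparison r was 0.245 and 0.075. With 186 and 96 features called for knockdown and 0 for rapamycin, 0 calls were shared and 0 would be by independent lists. The 2 constructs, each against sh GFP arrays of its own letter, gave effects that correlated at r = 0.416 (rho = 0.382). By itself sh p73-1 called 36 higher and 16 lower features and sh p73-2 called 33 and 22. Of these 18 and 1 were shared, where independent lists would share 0.0425 and 0.0126. Both construct effects use the same estimate of the spread of each feature, so here too the excess is overstated. The test of the difference between constructs gave 0 features by limma, with 1996 at an unadjusted p under 0.05 and a smallest adjusted p of 0.176, that of NUS1.

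The interval tracks held 7678 entries headed Veh and 8165 headed Rap, read here as vehicle and rapamycin, with median widths of 387 and 393 bp that covered 3.66 and 3.92 megabases. No replicate of either track was analysed here. Of the Veh intervals 6011 (78.3%, 95% interval 77.3 to 79.2) overlapped a Rap interval, and of the Rap intervals 6006 (73.6%, 72.6 to 74.5) overlapped a Veh interval. The highest deposited score in both, 41.636 and 44.67, belonged to the same interval on chromosome 9 (1697313 to 1697612, genome build not given in the sources used here, so no gene is named). Over 6011 overlapping pairs the scores of the tracks correlated at r = 0.922 on the log2 scale (rho = 0.846). Intervals without a partner had lower median scores, 3.0 in Veh and 3.12 in Rap, than those with one, 4.01 and 4.27. The lowest peak scores were 2.501 in Veh and 2.506 in Rap. The active regions, 9825, overlapped both tracks in 5999 cases, Veh alone in 1667 and Rap alone in 2159. Intervals without a partner were spread unevenly over blocks of chromosomes. Chromosomes 15, 18, 20 and 4 held 60 such in Veh and 551 in Rap, and chromosomes 16, 5 and 7 held 515 and 94. The median log2 ratio of Rap to Veh scores over overlapping pairs was 0.262 in the former block and -0.09 in the latter. The ratio of Rap to Veh intervals was 1.063 over the genome and ranged from 0.69 to 1.6 between blocks of chromosomes that follow each other in the table.

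**Figure D3:**
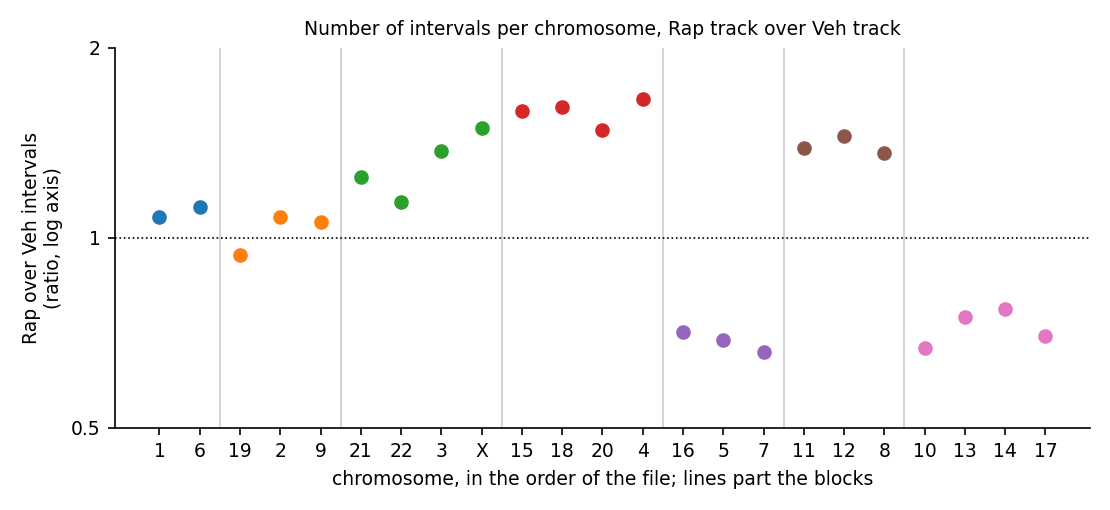
Number of Rap intervals over number of Veh intervals (vertical log axis) for each chromosome, in the order of the deposited table; points are chromosomes, colours and vertical lines mark the 7 blocks, and chromosome Y is not drawn. Ratios are 1.48 to 1.66 on chromosomes 15, 18, 20 and 4 and 0.66 to 0.71 on chromosomes 16, 5 and 7.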

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

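The tests on intervals per chromosome were chosen after the ratios had been seen, and those on the constructs before. The results given here are those for which a test of the difference between groups passed its threshold, and genes that led such a difference.

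The rapamycin effect differed between sh GFP and sh p73 cells for 13 lists by camera at the preset correlation, while 0 features passed by limma (2824 higher and 341 lower at an unadjusted p under 0.05). None of the 13 passed with an estimated correlation (smallest adjusted p = 0.569 with an estimated correlation), and fry called 0 lists. Camera compares a list with all other genes, and the median interaction over all features was 0.0741. Relative to that, all 13 were shifted downwards, with list medians between -0.105 and 0.002: oxidative phosphorylation (adjusted p = 9.95e-09), ATF4 genes (3.16e-05), glycolysis and ribosome biogenesis (0.000383 each), translation factors (0.00113), G2/M genes (0.00229), histones and autophagy (0.00527 each), lysosome (0.00718), nucleotide synthesis (0.0133), ribosomal proteins (0.0259), and interferon response and the unfolded protein response (0.036 each). For ribosomal proteins the median of 0.002 had the opposite sign to the mean of -0.007 and the test.

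The knockdown effect differed between constructs for 15 lists by camera at the preset correlation, with 0 features past the threshold by limma (1271 higher and 725 lower at an unadjusted p under 0.05) and a median of 0.0365 over all features. None of the 15 passed with an estimated correlation (adjusted p = 0.494 with an estimated correlation for all), and fry called 0. Relative to all other genes, lower with sh p73-2 were G2/M genes (adjusted p = 3.36e-05), lysosome and ATF4 genes (7.71e-05 each), oxidative phosphorylation (0.000203), ribosomal proteins (0.000623), interferon response (0.000701), the unfolded protein response and hypoxia (0.00123 each), glycolysis (0.00209), histones (0.00232), fatty acid synthesis (0.00409), autophagy (0.0145), cholesterol synthesis (0.0161) and extracellular matrix (0.0218), and higher were neural markers (0.0121).

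The 5 genes with the smallest p among those lower with sh p73-2 than with sh p73-1 were NUS1, METAP2, PABPC4, NDUFB11 and MAP3K20, none past the threshold (adjusted p = 0.176, 0.266, 0.266, 0.266 and 0.306). Against the sh GFP arrays of its own letter sh p73-2 gave -1.26, -0.99, -1.13, -0.90 and -0.87, whereas the median effect of sh p73-1 on them was 0.048. In the sh GFP arrays B lay above A by a median of 0.053, which does not decide on a difference between the letters, because the model that chose these genes had already removed it. An effect of sh p73-2 beyond p73, for instance on transcripts that match its sequence, is a candidate explanation. These values cannot decide on it, because the genes were chosen for lying lower with sh p73-2 than with sh p73-1. TP73 changed by -0.77 with sh p73-2 and by -1.19 with sh p73-1, but that difference did not pass the threshold. The values rest on 2 arrays per construct, and a p73 response that differs between constructs stays open.

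The Rap to Veh ratio of interval numbers differed between 7 blocks of chromosomes far beyond counting error (p = 2.57e-69, chi-square of 335.0 on 6 degrees of freedom, which ignores that the tracks overlap). Ratios were 1.09, 1.06, 1.34, 1.6, 0.69, 1.4 and 0.71, so that 5 blocks held more Rap intervals and 2 held fewer. Block explained 97.5% of the variation between chromosomes, against a median of 26.6% when chromosomes were permuted over blocks (permutation p = 0.0001, the smallest that the permutations made could give). A response of single chromosomes stays open: within blocks the chi-square was 8.4 on 17 degrees of freedom (p = 0.96) for all intervals, most of which the tracks share, but 29.4 (p = 0.031) for intervals without a partner, with p = 0.0068 in block 2 and 0.0082 in block 7, against 1272.8 between blocks. Measurement or calling of chromosomes in sets, such as arrays that each carry some chromosomes, is a candidate source of the differences, while a rapamycin effect on the genome as a whole was not tested and stays open.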

How the results depend on the processing

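The overlap of at least 50% of both intervals and the blocks of chromosomes were chosen after the data were seen; all other alternatives were planned. Leaving out the dimmest probe sets was not run, since centred values hold no level, and signal over background is unknown for the same reason. The cause of the changes was not tested unless stated.

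Features past the threshold under each alternative are given against the main counts. With a 1.5-fold minimum, stricter by construction, knockdown in vehicle had 141 features (main 282), rapamycin sh p73 against vehicle sh GFP 196 (479), rapamycin sh GFP against vehicle sh p73 125 (289), rapamycin over both hairpins 8 (25) and knockdown over both treatments 83 (836). With an adjusted p under 0.1, looser by construction, these were 1804, 1338, 805, 226 and 1894, and knockdown in rapamycin had 165 (48). With only probe sets of 1 symbol, knockdown in vehicle had 826, knockdown in rapamycin 88, rapamycin sh GFP against vehicle sh p73 629 and rapamycin over both hairpins 142. With array weights, the crossed comparisons had 935 and 158, rapamycin over both hairpins 665 and knockdown over both treatments 2633. In fits of only the 2 groups compared, which have fewer arrays, knockdown had 0 in vehicle and 1 in rapamycin, rapamycin in sh p73 cells 0 (4), and the crossed comparisons 228 and 0. Rapamycin in sh p73 cells also had 0 after quantile normalization, with each probe set by itself and with robust eBayes. By itself sh p73-1 called 52 features and sh p73-2 called 55, from fewer arrays. Other alternatives, array median centring among them, stayed within 1.5 times of the main count.

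In the comparisons of groups the letters were not used for pairing, unlike in the effects per construct, which were taken against sh GFP arrays of the same letter. Deviations of the same letter correlated between -0.137 and 0.232 over the 6 pairs of groups. The pairs within a hairpin gave 0.145 for sh GFP and 0.232 for sh p73, where the letter is also the construct. With the letter as a replicate block, knockdown had 161 in vehicle and 1 in rapamycin, rapamycin in sh p73 cells 0, the crossed comparisons 309 and 162, rapamycin over both hairpins 9 and knockdown over both treatments 644.

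Leaving out each array in turn gave 0 to 1 features for rapamycin in sh GFP cells (1 without vehicle sh GFP A), 3 to 183 for knockdown in vehicle, 0 to 0 for rapamycin in sh p73 cells, 0 to 29 for knockdown in rapamycin, 1 to 539 and 0 to 146 for the crossed comparisons, 0 to 1 for the interaction (1 without vehicle sh GFP B), 0 to 11 for rapamycin over both hairpins, 184 to 972 for knockdown over both treatments and 0 for the difference between constructs. The correlation of rapamycin effects ranged from -0.058 to 0.25, with -0.058 without vehicle sh GFP B and -0.045 without rapamycin sh GFP A, that of knockdown effects from 0.18 to 0.496 and that of rapamycin with knockdown from 0.216 to 0.631.

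Lists past the set test numbered 13, 9, 14, 10, 13, 19, 13, 18, 11 and 15 in the order rapamycin in sh GFP cells, knockdown in vehicle, rapamycin in sh p73 cells, knockdown in rapamycin, both crossed comparisons, interaction, rapamycin over both, knockdown over both and constructs. With an estimated correlation there were 0 in each. With fry there were 1, 1, 7, 0, 1, 9, 0, 11, 3 and 0.

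Of the named genes past the threshold, 27 of 54 for knockdown over both treatments passed whichever array was left out, against 0 of 19 for rapamycin over both hairpins. Over 12828 alternative values of 716 named results, 1320 lost the threshold, 294 gained it, 11214 kept their side and 0 changed direction while called. Only the 195 named results past the threshold in the main fit could lose it, and just 8 of these 195 lost it in no alternative.

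With an overlap of at least 50% of both intervals 74.3% of Veh and 69.9% of Rap intervals had a partner. Among the better scoring upper part of each track, which leaves fewer intervals, each set against the whole other track, the shares were 95.5% and 91.1%. Among intervals that scored at least the median over both tracks, the ratio of Rap to Veh intervals was 1.143. In blocks 3 to 7 that ratio was 1.34, 1.6, 0.69, 1.4 and 0.71, with blocks 5 and 7 on the other side of 1.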

Other observations

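The scaling test was chosen after the result was seen; the splits of the arrays and the test of the control hairpin were not.

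Several lists had medians of opposite sign with rapamycin and with p73 knockdown, 2 effects that the balanced design estimates independently. All of them passed camera at the preset correlation in both comparisons. None passed with an estimated one (adjusted p = 0.688 for each with knockdown, 0.105 or more with rapamycin), and the opposition itself was not tested. Vehicle sh p73 and rapamycin sh GFP enter the 2 effects with opposite signs, so a shift in either group alone could give the opposition. The interaction passed camera at the preset correlation only for G2/M genes, histones, ATF4 genes and ribosomal proteins among these lists (adjusted p = 0.00229, 0.00527, 3.16e-05 and 0.0259). Medians of G1/S genes were -0.11 with rapamycin and 0.09 with knockdown, of G2/M genes -0.09 and 0.07, of histones -0.16 and 0.08 and of ATF4 genes -0.16 and 0.06. Muscle differentiation genes had 0.06 and -0.08, and ribosomal proteins 0.07 and -0.06. Autophagy genes had a median of 0.05 with each. CCND1 rose by 0.63 with knockdown and stood at -0.25 with rapamycin (adjusted p = 0.119), and PSAT1, an enzyme of serine synthesis, rose by 0.37 and stood at -0.41 (adjusted p = 0.0726).

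More genes were higher than lower after p73 knockdown, 705 against 131. In all, 34 splits of the 8 arrays into 4 and 4 can be fitted beside the treatment. Only 1, the real one, gave 836 features or more, and the highest of the others gave 0. The other splits leave the knockdown effect in their spread, which lowers their counts, and 1 of 34 is the smallest share possible. The splits therefore do not exclude chance for the number of calls, and they do not test the balance of rises and falls. After quantile normalization 73.6% of calls were still higher (exact 95% interval 70.9 to 76.2), which argues against scaling between arrays as the whole cause. The interval treats features as independent, which they are not, so it covers counting error only. At an unadjusted p under 0.05 there were 2407 higher and 4227 lower features in vehicle, where the median change was -0.0375. In rapamycin there were 2976 and 528, with a median of 0.0418, so scaling as a part of the cause stays open. A lowering of the higher genes by the sh GFP hairpin, the only comparator, also stays open. The ratio of sh p73-2 to sh p73-1 effects on the higher genes was 0.855 in vehicle and 1.05 in rapamycin, against 0.642 and 0.799 for TP73, but it does not decide, because the fit that chose these genes counts a difference between constructs as spread and so favours equal effects, and the lower genes gave 1.03 and 0.883.

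For rapamycin over both hairpins, 1 of 34 splits of the arrays, the real one, gave 25 features or more. The highest of the others gave 1. The other splits leave the rapamycin effect in their spread, which lowers their counts, and 1 of 34 is the smallest share possible. The splits therefore do not exclude chance for the count. With 1 array left out the count was 0 in 4 of 8 fits (without vehicle sh GFP B, vehicle sh p73 B, rapamycin sh GFP A or rapamycin sh p73 A) and 2, 11, 7 and 1 without vehicle sh GFP A, vehicle sh p73 A, rapamycin sh GFP B and rapamycin sh p73 B.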
